A study of Homo sapiens with 12 samples.

How the data were processed

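Total RNA from 12 samples of Ramos and SK-N-BE2 cells, infected with a control sgRNA or a USP29 sgRNA and selected with puromycin for 48 hours, had been treated with DNase and made into libraries with standard Illumina protocols, per the labels' protocols. The submitters' processing notes list the aligner HISAT2 2.0.4, the assembler StringTie 1.3.0, edgeR without a version, and the genome build GRCh38 (hg38), with no order or parameters. The counting tool, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The authors deposited a table of 50868 Ensembl genes with whole-number counts per library, which summed to different totals, and FPKM per library. Whether the deposited counts are reads counted per gene or rounded StringTie estimates is not stated, so reads shared by overlapping genes, antisense genes or pseudogenes may have been split between them. Between libraries, the deposited FPKM per count differed by the ratio of the count totals to within a relative deviation of 1.77e-05 over the 9463 genes with 50 or more counts in every library, so the authors' FPKM carry no scaling beyond the total. No count was found for 16619 genes, 375 IDs share their symbol with another ID, and 50111 IDs were found in GENCODE v29 (47538 with the same start and end), which gave the gene types. Coordinates are those of the deposited table, counted from 1.

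Groups came from the labels: 2 cell lines by 2 sgRNAs, with 3 libraries each. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 10.9 or more). Totals were 16479042 to 24317552 counts, so that a count of 0 allowed 0.123 to 0.182 CPM (3 counts of the total). In SK-N-BE2 the USP29 sgRNA libraries were shallower than the controls.

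The tests, gene lists, rule for named genes and alternatives were set before the data were examined, except where the text says that a choice was made after seeing the data. In each line the deposited counts of 3 USP29 sgRNA and 3 control libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10) and TMM normalization, without a replicate block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p-values of single genes come from this test unless another tool is named. The difference between the lines was the interaction term of a fit over all 12 libraries, coded as the SK-N-BE2 change minus the Ramos change. Shared calls were compared with the overlap expected of independent lists and with Fisher's exact test over the genes tested in both lines. The lines have separate controls.

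The 28 lists held glycolysis, HIF1 and hypoxia targets outside glycolysis, MYC core targets and ribosome biogenesis, nucleotide synthesis, glutamine and amino acid transport and use, serine and one-carbon, fatty acid synthesis, cholesterol synthesis, the TCA cycle, the nuclear-encoded respiratory chain, cytosolic ribosomal proteins, S phase, G2/M phase, p53 targets, apoptosis regulators, the unfolded protein and integrated stress response, the interferon response, NF-kB and inflammatory targets, B cell identity, neuroblastoma adrenergic identity, mesenchymal and fibroblast, T cell, myeloid, and epithelial and kidney cell markers, replication-dependent histones, mitochondrially encoded mRNA, PEG3 domain neighbours of USP29, and immediate early genes. Lists with 5 or more tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Some lists had larger p-values there although their estimated correlation was below 0.01. Examples are MYC core targets in Ramos (-0.003, unadjusted camera p 0.00933 and then 0.0396) and NF-kB targets in SK-N-BE2 (-0.09, 0.00076 and then 0.0238). A call lost with an estimated correlation therefore does not by itself show that the genes of a list vary together. Tests of lists added after seeing the data were adjusted over their own family of 7. Member counts are given over all genes tested and adjusted over the list alone.

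Named genes were USP29, MYC, MYCN, HIF1A, EPAS1, MAX and ARNT, and per line the 8 genes with the largest increase and the 8 with the largest decrease. These had to pass the test, carry a gene name other than that of a clone, long intergenic, antisense or small RNA or pseudogene, reach a mean log2 CPM of 2 in the higher group, and have all 3 libraries of 1 group above all 3 of the other. From each list up to 2 members with the smallest adjusted p were named, and between the lines up to 5 shared genes per direction and up to 5 per direction with the largest difference. Members beyond these were chosen after their values were seen. Some genes that the rule picked are not reported here. Levels are in CPM, given as mean ± SD over 3 libraries where a group is described. Group levels of single genes use library totals scaled by TMM within the line, sums over lists use TMM over all 12 libraries, and levels and limits of single libraries and sums over marker or olfactory receptor genes use the unscaled total. The log2 fold changes carry the SE of the fit.

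On counts simulated from the real means and totals with 200 genes changed and a biological coefficient of variation of 0.13, the edgeR step recovered 38.8%, 97.0% and 100% of genes changed by 1.5, 2 and 4 times in Ramos (13777 genes), 47.8%, 89.6% and 100% in SK-N-BE2 (16412 genes), and 8.96%, 77.6% and 100% for the difference between the lines (17926 genes). Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, limma-trend on log2(FPKM + 1), a replicate block, each library left out in turn, a minimum change of 1.5-fold, an adjusted p under 0.01, and both lines fitted together. Robust estimation, protein-coding genes alone, the removal of genes over 1000 times higher in the other line, the removal of 2 Ramos libraries, thinning to 16479042 counts and a restriction to genes tested in both lines were added after seeing the data. The symbol filter of the naming rule was corrected after values were seen, since it had left out protein-coding genes whose names resemble those of pseudogenes. Overlaps of splits were computed with 100 drawn pairs. Permutation tests were run in R. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.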

Results

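Messenger RNA levels were measured in 2 human tumor cell lines. Ramos is a B cell line from a Burkitt lymphoma, a tumor in which the MYC gene is rearranged. SK-N-BE2 is a neuroblastoma line with amplified MYCN, the neural relative of MYC. Each line was infected to carry either a control sgRNA or an sgRNA against USP29, a deubiquitinase gene, and was kept under puromycin for 48 hours, so that uninfected cells were removed. The sgRNA is the RNA that directs Cas9 to its target. The titles mark all USP29 sgRNA libraries of both lines as sg2, and whether this stands for a single guide is not stated. If it does, effects of that guide at other sites cannot be told apart from loss of USP29. This also holds for changes shared by both lines. The 12 libraries fell into 4 groups of 3, with 16479042 to 24317552 counts per library. Totals were 17691285 ± 1391036 counts in Ramos controls and 19351856 ± 1695416 counts in Ramos USP29 sgRNA libraries (mean ± SD, n = 3 each). In SK-N-BE2 they were 22375548 ± 2092861 counts in controls and 16995756 ± 764996 counts with the USP29 sgRNA. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The title of the series ties USP29 to the stabilization of MYC and HIF1α and to tumor metabolism. The comparisons therefore covered the transcripts of MYC and HIF family genes, their target genes and the genes of metabolism.

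USP29 (ENSG00000131864, chromosome 19, 57119138 to 57131926, plus strand, GRCh38) had no count in 9 of the 12 libraries, among them the 3 SK-N-BE2 controls and all 6 Ramos libraries. A count of 0 allowed up to 0.182 CPM (counts scaled to the library total) in the library with the lowest total and 0.123 CPM in the one with the highest. The SK-N-BE2 USP29 sgRNA libraries held 1, 3 and 5 USP29 counts, or 0.0559, 0.180 and 0.303 CPM. On the log2(CPM + 1) scale these libraries lay 0.23 above the controls, and on the log2(CPM + 0.1) scale 1.38, so the size rests on the pseudocount (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). At this depth USP29 mRNA was close to or under the detection limit in every group, so its level could not check which libraries carried the targeting sgRNA. An edit that ends a reading frame need not lower the mRNA. Limits from counts of 0 cover counting error only.

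The markers of each line followed the labels. The 20 listed B cell identity genes summed to 7096 ± 144 CPM in Ramos controls and to 546 CPM in SK-N-BE2 controls. The 22 adrenergic neuroblastoma genes summed to 7836 ± 340 CPM in SK-N-BE2 controls and to 0.820 ± 0.260 CPM in Ramos controls (SD, n = 3). In Ramos USP29 sgRNA libraries the latter sum was 2.87 ± 1.54 CPM. Over 308 genes abundant in SK-N-BE2 and nearly absent from Ramos, the Ramos controls and USP29 sgRNA library 1 stood at 0.0311 to 0.0402% of the SK-N-BE2 level, and USP29 sgRNA libraries 2 and 3 at 0.102% and 0.0935%.

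In Ramos, 9 of 23 tested glycolysis genes and 10 of 18 other HIF1 and hypoxia targets were lower with the USP29 sgRNA. PDK1, the kinase that inhibits pyruvate dehydrogenase, fell from 227 ± 12.2 to 138 ± 9.74 CPM (SD, n = 3 each). FAM162A, a hypoxia-induced mitochondrial protein gene, fell from 346 ± 22.9 to 199 ± 6.28 CPM and the glycolytic kinase gene PGK1 from 1100 ± 23.4 to 770 ± 15.0 CPM. ATF4, the central transcription factor of the integrated stress response, fell from 500 ± 4.75 to 338 ± 22.4 CPM, and asparagine synthetase, ASNS, from 280 ± 16.7 to 147 ± 4.06 CPM. Of 24 G2/M genes 18 fell, while 7 of 17 interferon response genes rose, among them OAS2, an antiviral RNA sensor, from 39.8 ± 0.836 to 71.9 ± 3.61 CPM. In total 2445 of 13767 tested genes changed (17.8%), 1147 up and 1298 down (edgeR quasi-likelihood test, adjusted p under 0.05). Of these 264 and 98 changed by 2-fold or more. The balance turned with both lines fitted together (1817 up and 1101 down), with limma-trend on log2(FPKM + 1) (1232 and 938) and at 1.5-fold or more (484 and 295).

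Among the largest increases in Ramos were those of the adhesion gene PCDH9 at a log2 fold change of 2.45 ± 0.45 (SE), the kinesin KIF26B at 2.13 ± 0.31 and the stress kinase MAPKAPK3 at 2.10 ± 0.13. They were followed by the interferon-induced chemokine CXCL10 at 2.05 ± 0.17, the growth factor receptor FGFR1 at 2.04 ± 0.19 and GPD2, the mitochondrial glycerol phosphate dehydrogenase, at 1.93 ± 0.25. Adjusted p-values of these 6 genes ran from 0.000624 to 0.0116. NUDT16, a nucleotide hydrolase, stood at 2.03 ± 0.55 (adjusted p = 0.0408). Its call was lost when control 1, 2 or 3 or USP29 sgRNA library 1 or 3 was left out (highest adjusted p = 0.118). The largest decrease was in JPH2, a junctophilin (ENSG00000149596, chromosome 20, 44111695 to 44187578). It fell by 2.51 ± 0.13 from 8.70 ± 0.425 to 1.52 ± 0.0458 CPM (adjusted p = 0.000452). It was followed by the inhibin subunit gene INHBE at -1.88 ± 0.14 and the glutathione-degrading enzyme gene CHAC1 at -1.80 ± 0.23. Then came the sphingomyelinase SMPD3 at -1.65 ± 0.17, ZNF268 at -1.60 ± 0.17, SERINC2 at -1.58 ± 0.12 and MYADM at -1.55 ± 0.22. Adjusted p-values from INHBE to MYADM ran from 0.000903 to 0.00545. A Y-linked gene that the rule also picked is not given.

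Transcripts of the MYC and HIF families did not pass the test in Ramos. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) was at 4.99 ± 3.20 CPM in controls and 5.23 ± 2.11 CPM with the USP29 sgRNA, a log2 fold change of 0.06 ± 0.49 (adjusted p = 0.951). Its counts were 39, 162 and 68 in the controls and 105, 144 and 57 in the others. This level is low for a Burkitt lymphoma line and uneven between replicates, for reasons not found here. The result therefore does not show that MYC mRNA was unchanged. HIF1A, the oxygen-regulated subunit of HIF1, stood at 0.16 ± 0.09 (adjusted p = 0.281, 161 to 179 CPM). Its partner ARNT stood at 0.11 ± 0.15 (0.643) and the MYC partner MAX at 0.17 ± 0.14 (0.420). MYCN and EPAS1, the gene of HIF2α, had too few counts to be tested in Ramos.

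Of the metabolic lists in Ramos, those of glycolysis, hypoxia, glutamine use and fatty acid synthesis were lower by camera with the preset correlation, and none with an estimated correlation. Of 23 tested glycolysis genes, 9 fell and 0 rose (11 and 1 adjusted over the list alone). The median log2 fold change was -0.24 (camera adjusted p = 0.000114, adjusted p = 0.226 with an estimated correlation). Of 18 HIF1 and hypoxia targets outside glycolysis, 10 fell and 1 rose (13 and 3 adjusted over the list alone). Their median was -0.49 (camera adjusted p = 0.000545, and adjusted p = 0.216 with an estimated correlation). Among them DDIT4, a brake on mTORC1, fell by 0.93 ± 0.09 and the vascular growth factor VEGFA by 0.49 ± 0.09, while CITED2, a feedback inhibitor of HIF1, rose by 0.86. Glutamine and amino acid transport and use had 6 of 15 members lower (8 adjusted over the list alone), including the cystine transporter SLC7A11 at -0.35 ± 0.06. Their median was -0.18 (camera adjusted p = 0.0046, and adjusted p = 0.211 with an estimated correlation). Fatty acid synthesis had 4 of 11 lower (4 adjusted over the list alone), with the desaturases SCD at -0.58 ± 0.04 and FADS1 at -0.80 ± 0.11. Its median was -0.12 (camera adjusted p = 0.0295, and adjusted p = 0.226 with an estimated correlation). This last list call was lost without control 3 (0.0519), USP29 sgRNA library 2 (0.0556) or 3 (0.0517).

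Serine and one-carbon genes had 5 of 12 lower and 1 higher in Ramos (5 and 1 adjusted over the list alone), with the serine synthesis enzymes PSAT1 at -0.54 ± 0.06 and PHGDH at -0.50 ± 0.06. The list as a whole did not pass (adjusted p = 0.110). Nucleotide synthesis had 5 lower and 2 higher of 24 (7 and 2 adjusted over the list alone), among them the purine enzymes PPAT at -0.25 ± 0.05 and ATIC at 0.25 ± 0.04 (list adjusted p = 0.355). Cholesterol synthesis had 4 lower and 1 higher of 20 (5 and 1 adjusted over the list alone), led by the demethylase CYP51A1 at -0.91 ± 0.07 and the sterol carrier STARD4 (list adjusted p = 0.465). The TCA cycle had 3 lower and 1 higher of 25 (2 and 0 adjusted over the list alone), among them the subunits DLST at -0.43 ± 0.09 and SUCLG2 at -0.33 ± 0.08 (0.865). Of 31 nuclear-encoded respiratory chain genes CYC1 fell by 0.42 ± 0.08 and NDUFA4 rose by 0.34 ± 0.09. There 0 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.490). Of 13 mitochondrially encoded transcripts MT-ND4 was lower at -0.17 ± 0.05 (adjusted p = 0.0498, 0 adjusted over the list alone, list adjusted p = 0.994). The call of MT-ND4 was lost in all 6 omissions of a library (highest adjusted p = 0.141). Those of SUCLG2 and NDUFA4 were lost in 5 of 6, that of PPAT in 4 and that of DLST without control 3 or USP29 sgRNA library 2.

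MYC core targets and ribosome biogenesis genes in Ramos moved the other way: 9 of 35 rose and 0 fell (10 rose and 3 fell adjusted over the list alone). Examples were the ribosome assembly factor RRP9 at 1.00 ± 0.11 and the G1 kinase CDK4 at 0.58 ± 0.07. The median was 0.15 (camera adjusted p = 0.028, adjusted p = 0.211 with an estimated correlation). This call was lost without control 2 (0.0586), control 3 (0.0519) or USP29 sgRNA library 3 (0.0585). Cytosolic ribosomal protein genes showed no list change, with 1 higher and 1 lower, RPL8 at -0.46 ± 0.05, among 32 (1 and 1 adjusted over the list alone, list adjusted p = 0.865). G2/M genes fell in 18 of 24 cases (20 adjusted over the list alone), among them the mitotic motors CENPE at -0.51 ± 0.06 and KIF23 at -0.51 ± 0.07. Their median was -0.26 (camera adjusted p = 9.39e-07, and adjusted p = 0.211 with an estimated correlation). S phase genes had 3 lower and 1 higher of 22 (3 and 1 adjusted over the list alone), including the helicase subunit MCM2 at -0.32 ± 0.07 and GINS1 (list adjusted p = 0.445). The call of GINS1 was lost in 5 of 6 omissions (highest adjusted p = 0.0872) and that of MCM2 without control 1 or 3. Of 21 p53 targets 7 fell (7 adjusted over the list alone), with the cell cycle inhibitor CDKN1A at -0.61 ± 0.07 and SESN2 at -0.64 ± 0.08. Their median was -0.22 (camera adjusted p = 0.0046, and adjusted p = 0.216 with an estimated correlation).

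Among the other Ramos lists, 7 of 17 interferon response genes rose and 0 fell (7 and 0 adjusted over the list alone), with OAS2 at 0.85 ± 0.06 and IFIT3 at 1.52 ± 0.19. Their median was 0.39 (camera adjusted p = 0.000545, adjusted p = 0.211 with an estimated correlation). The OAS2 call was absent when both lines were fitted together (adjusted p = 0.199). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 4 of 10 higher (9 adjusted over the list alone), such as HIST1H2BK at 1.59 ± 0.14 and HIST1H4H at 2.25 ± 0.24. Its median was 1.12 (camera adjusted p = 1.25e-05, and adjusted p = 0.211 with an estimated correlation). NF-kB and inflammatory targets had 6 higher and 3 lower of 16 (7 and 3 adjusted over the list alone), led by TRAF1 at 0.78 ± 0.06 and CD83 at 0.70 ± 0.06 (list adjusted p = 0.0891). B cell identity genes had 8 higher and 4 lower of 19 (10 and 5 adjusted over the list alone), including the transcription factor IKZF1 at 0.45 ± 0.04 and HLA-DRA at 0.38 ± 0.04 (0.110). Unfolded protein and integrated stress genes had 7 lower and 4 higher of 25 (9 and 6 adjusted over the list alone), with CEBPG at -0.55 ± 0.05 beside ATF4 at -0.57 ± 0.06 (0.0837). Apoptosis regulators had 2 higher and 1 lower of 20 (3 and 1 adjusted over the list alone), the survival genes BCL2A1 at 1.07 ± 0.08 and BCL2L1 at 0.58 ± 0.06 among them (0.465). Immediate early genes had 2 higher and 2 lower of 13 (2 and 4 adjusted over the list alone, list adjusted p = 0.234). The call of EGR2 at 1.31 ± 0.33 was lost in all 6 omissions (highest adjusted p = 0.106), and that of JUN at 0.82 ± 0.20 in 5 of 6.

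Markers of other cell types in Ramos were few. The T cell list had 4 tested members, with the kinase gene LCK lower at -1.16 ± 0.08, IL7R higher at 0.94 ± 0.11 and TRAC lower (1 higher and 2 lower adjusted over the list alone). In the mesenchymal list YAP1 rose by 1.85 ± 0.22 and COL1A1 by 0.72 ± 0.10 among 6 (3 adjusted over the list alone, list adjusted p = 0.0891). The myeloid list had CSF1R higher at 1.73 ± 0.14 among 5 (1 adjusted over the list alone, 0.445). No gene passed of 3 in the epithelial list (1 adjusted over the list alone) or of 3 neighbours of USP29 in the PEG3 domain (0 adjusted over the list alone). No adrenergic neuroblastoma gene had enough counts to be tested. Of the 24 Ramos lists with 5 or more tested members, camera called 9 with the preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 17. The count of 2445 fell to 1472, 1262 or 1268 without control 1, 2 or 3, to 1531 without USP29 sgRNA library 1 and to 1385 without library 2. Without both USP29 sgRNA libraries 2 and 3, a comparison chosen after seeing the data, 252 genes passed, with 1 library against 3 and the spread taken from the controls alone.

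In SK-N-BE2, 14 of 16 mesenchymal genes were higher and 13 of 22 adrenergic nerve cell genes lower with the USP29 sgRNA. FN1, which encodes fibronectin, rose from 406 ± 9.98 to 3443 ± 31.6 CPM (SD, n = 3 each). CHGA, which encodes chromogranin A of neurosecretory granules, fell from 826 ± 19.1 to 226 ± 16.1 CPM. IGF2, an imprinted fetal growth factor gene, fell from 225 ± 1.24 to 10.97 ± 0.681 CPM. Of 24 glycolysis genes 15 fell, with PDK1 at 78.5 ± 9.95 CPM in controls and 22.9 ± 1.08 CPM with the USP29 sgRNA. So did 25 of 35 MYC core targets and 17 of 22 S phase genes. Altogether 6240 of 16446 tested genes changed (37.9%), 3240 up and 3000 down (edgeR quasi-likelihood test, adjusted p under 0.05). By 2-fold or more 1116 rose and 392 fell.

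Of the MYC and HIF family transcripts in SK-N-BE2, MYCN fell and EPAS1 and HIF1A rose, while MYC and ARNT did not pass. MYCN (ENSG00000134323, chromosome 2, 15940564 to 15947007), the amplified gene of this line, fell by 0.62 ± 0.03 on the log2 scale from 4269 ± 134 to 2784 ± 74.7 CPM (adjusted p = 1.85e-05). With both lines fitted together it did not pass (adjusted p = 0.0868). EPAS1 (ENSG00000116016, chromosome 2, 46293667 to 46386703) rose by 2.81 ± 0.13 from 3.03 ± 0.503 to 21.3 ± 0.588 CPM (adjusted p = 9.74e-06). HIF1A (ENSG00000100644, chromosome 14, 61695513 to 61748259) rose by 0.46 ± 0.09 from 346 ± 26.1 to 475 ± 49.7 CPM (adjusted p = 0.00548). MAX fell by 0.31 ± 0.08 (adjusted p = 0.0244), a call lost without control 1, control 3, USP29 sgRNA library 1 or library 3 (highest adjusted p = 0.0744), with both lines fitted together (0.0991) and with a replicate block (0.0671). ARNT stood at -0.17 ± 0.10 (adjusted p = 0.219), and passed without control 3 at -0.26 (0.0294). MYC stood at 0.91 ± 0.67 (adjusted p = 0.329), with 70, 43 and 54 counts in controls and 135, 94 and 11 in the others. Without USP29 sgRNA library 3, the last of these, it passed at 1.42 (0.00438).

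The largest increases in SK-N-BE2 with counts in both groups were in NAV3, a neuron navigator gene (4.68 ± 0.28, 0.464 to 12.4 CPM), the salivary peptide gene HTN1 (4.30 ± 0.21), FLT1, a receptor for VEGF (4.24 ± 0.26) and the transcription factor TFAP2C (4.10 ± 0.38). Others were the collagenase MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160) at 4.01 ± 0.11 (3.68 ± 0.249 to 59.4 ± 6.25 CPM), the thrombin receptor family gene F2RL2 and the growth factor FGF5 (3.78 ± 0.18). Adjusted p-values of these 7 genes ran from 1.74e-06 to 0.000224. INO80B-WBP1, a read-through of 2 neighbouring genes (chromosome 2, 74455088 to 74460884), had 0 counts in the 3 controls and 47, 191 and 162 with the USP29 sgRNA (adjusted p = 0.00421). INO80B, which it overlaps, had 182, 239 and 196 counts in the controls and 205, 67 and 61 in the others, so this value is uncertain. The largest decreases were in IGF2 (ENSG00000167244, chromosome 11, 2129112 to 2141238) at -4.36 ± 0.06 (adjusted p = 8.45e-08). They were followed by the melanin synthesis gene DCT at -4.18 ± 0.20 (7.24 ± 0.646 to 0.394 ± 0.0931 CPM) and NDUFA4L2, a hypoxia-induced subunit gene of the respiratory chain, at -4.12 ± 0.54 (13.3 ± 7.82 to 0.757 ± 0.351 CPM, adjusted p = 0.00116). Next were the calcium binding protein gene CABP7 at -3.47 ± 0.12, the phosphodiesterase PDE4C at -3.47 ± 0.24, the neurexophilin NXPH4 at -3.43 ± 0.27 and the neuronal transcription factor NEUROD1 at -2.88 ± 0.21 (adjusted p from 4.27e-06 to 0.000101). PCDHGA8 at -3.75 ± 0.55 shares exons with the other gamma protocadherins and is uncertain. DCT was present in Ramos USP29 sgRNA libraries 2 and 3 at 7.80 CPM or more, near its level in the SK-N-BE2 controls. In the other Ramos libraries it was at 0.363 to 0.624 CPM.

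Of the metabolic lists in SK-N-BE2, those of glycolysis, nucleotide, serine and fatty acid synthesis and the respiratory chain were lower by camera with the preset correlation, and none with an estimated correlation. Glycolysis had 15 of 24 members lower and 2 higher (16 and 2 adjusted over the list alone), among them PDK1 at -1.78 ± 0.10 and GPI, the phosphoglucose isomerase, at -0.88 ± 0.05. Its median was -0.26 (camera adjusted p = 0.000362, adjusted p = 0.108 with an estimated correlation). The 2 that rose were PFKP at 0.59 and the glucose transporter gene SLC2A3 at 0.97. Of 28 HIF1 and hypoxia targets 13 fell and 5 rose (13 and 5 adjusted over the list alone), and the list did not pass. Their median was -0.26 (camera adjusted p = 0.0641). The hypoxia-induced carbonic anhydrase CA9 at -2.91 ± 0.32, the mitophagy receptor BNIP3 at -1.11 ± 0.08 and VEGFA at -0.92 ± 0.10 fell. Those that rose included ANGPTL4 at 1.70, CA12 at 1.11, the glycoprotein STC2 at 1.09 ± 0.05 and P4HA2 at 1.04. Nucleotide synthesis had 16 of 24 lower (18 lower and 1 higher adjusted over the list alone), for example PPAT at -0.45 ± 0.04 and NME1 at -0.42 ± 0.04. Its median was -0.26 (camera adjusted p = 3.5e-05, and adjusted p = 0.0518 with an estimated correlation). Serine and one-carbon genes had 8 of 14 lower (9 lower and 1 higher adjusted over the list alone), with MTHFD1 at -0.41 ± 0.03 and MTR at -0.34 ± 0.03. Their median was -0.34 (camera adjusted p = 0.00284, and adjusted p = 0.0811 with an estimated correlation). Fatty acid synthesis had 7 of 13 lower and 1 higher (7 and 2 adjusted over the list alone), with SCD at -0.85 ± 0.02 and acetyl-CoA carboxylase, ACACA, at -0.49 ± 0.03. Its median was -0.11 (camera adjusted p = 0.0129, and adjusted p = 0.110 with an estimated correlation).

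Respiratory chain genes had 14 of 31 lower in SK-N-BE2 (14 adjusted over the list alone), for example ATP5B at -0.40 ± 0.06 and COX6C at -0.30 ± 0.05. Their median was -0.22 (camera adjusted p = 0.000678, adjusted p = 0.0912 with an estimated correlation). Glutamine and amino acid genes had 8 lower and 2 higher of 16 (8 and 2 adjusted over the list alone), the higher ones being SLC7A11 at 1.78 ± 0.05 and the amino acid transporter SLC38A2 (list adjusted p = 0.137). Cholesterol synthesis had 8 of 20 lower (8 lower and 1 higher adjusted over the list alone), with the sterol regulator SREBF2 at -0.16 ± 0.03 (0.0937). The TCA cycle had 7 of 25 lower (7 adjusted over the list alone), with pyruvate carboxylase, PC, at -0.56 ± 0.07 and MDH2 at -0.25 ± 0.03 (0.135). Mitochondrially encoded transcripts had 3 lower and 1 higher of 13 (2 and 1 adjusted over the list alone), with MT-CYB at 0.15 ± 0.02 and MT-ND4 at -0.15 ± 0.03 (0.210). The mitochondrial share of counts was 7.65 ± 0.146% in controls and 7.25 ± 0.113% with the USP29 sgRNA (SD, n = 3).

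Growth and division lists fell in SK-N-BE2. MYC core targets and ribosome biogenesis had 25 of 35 members lower and 0 higher (27 and 0 adjusted over the list alone), with the nucleolar genes NCL at -0.31 ± 0.03 and NPM1 at -0.35 ± 0.04. Its median was -0.24 (camera adjusted p = 5.69e-07, and adjusted p = 0.0472 with an estimated correlation). Cytosolic ribosomal proteins had 28 of 32 lower (30 adjusted over the list alone), such as RPL19 at -0.43 ± 0.03. Their median was -0.36 (camera adjusted p = 7.83e-09, and adjusted p = 0.0912 with an estimated correlation). S phase genes had 17 of 22 lower (19 adjusted over the list alone), with MCM2 at -0.50 ± 0.03 and MCM7. Their median was -0.40 (camera adjusted p = 1.39e-07, and adjusted p = 0.0472 with an estimated correlation). G2/M genes had 19 of 24 lower (21 adjusted over the list alone), among them the topoisomerase TOP2A at -0.63 ± 0.03, from 1186 ± 38.6 to 766 ± 7.91 CPM, and CENPF at -0.57 ± 0.03. Their median was -0.26 (camera adjusted p = 1.44e-07, and adjusted p = 0.0756 with an estimated correlation). In contrast 13 of 24 p53 targets rose and 3 fell (14 and 3 adjusted over the list alone), led by CDKN1A at 2.20 ± 0.08, from 6.15 ± 0.234 to 28.2 ± 1.68 CPM, and TP53I3 at 1.07 ± 0.06. Their median was 0.59 (camera adjusted p = 0.00132, and adjusted p = 0.0756 with an estimated correlation). Apoptosis regulators had 8 higher and 3 lower of 18 (8 and 3 adjusted over the list alone), with BMF at 0.82 ± 0.04 and BCL2 (list adjusted p = 0.0937).

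Cell identity lists moved in opposite directions in SK-N-BE2. Of 22 adrenergic neuroblastoma genes 13 fell and 5 rose (15 and 5 adjusted over the list alone), among them CHGA at -1.87 ± 0.06, CHGB at -1.51 ± 0.05 and the noradrenaline enzyme DBH at -1.91 ± 0.08. Higher members included RET at 1.00 ± 0.04. The list's median was -0.44 (camera adjusted p = 0.00118, and adjusted p = 0.0912 with an estimated correlation). Of 16 mesenchymal and fibroblast genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), with FN1 at 3.09 ± 0.03 and the smooth muscle gene TAGLN at 2.91 ± 0.06. Their median was 1.41 (camera adjusted p = 2.47e-08, and adjusted p = 0.0518 with an estimated correlation). Their summed level went from 3255 ± 393 to 8801 ± 119 CPM, and that of the adrenergic genes from 7836 ± 340 to 5575 ± 74.7 CPM (SD, n = 3). Immediate early genes had 12 of 16 higher (12 adjusted over the list alone), with CYR61 at 2.78 ± 0.05 and CTGF at 3.47 ± 0.07. Their median was 1.11 (camera adjusted p = 3.04e-07, and adjusted p = 0.0653 with an estimated correlation). NF-kB targets had 8 higher and 1 lower of 12 (8 and 1 adjusted over the list alone), including IER3 at 1.72 ± 0.06 and the chemokine CXCL8 at 2.97 ± 0.17. Its median was 0.71 (camera adjusted p = 0.00165, and adjusted p = 0.0775 with an estimated correlation). Interferon genes had 10 higher and 1 lower of 17 (10 and 1 adjusted over the list alone), with IRF9 at 1.14 ± 0.10 and OAS3 at -0.92 ± 0.06. Their median was 0.93 (camera adjusted p = 0.00337, and adjusted p = 0.294 with an estimated correlation). The summed level of the 26 listed interferon genes did not rise (214 ± 2.91 CPM in controls and 209 ± 23.5 CPM with the USP29 sgRNA). Of these genes 12 reached a mean of 1 CPM in controls and 17 with the USP29 sgRNA.

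Unfolded protein and integrated stress genes had 13 higher and 2 lower of 25 in SK-N-BE2 (15 and 2 adjusted over the list alone), with the disulfide isomerase PDIA4 at 0.49 ± 0.03 and the lipoprotein receptor VLDLR at -0.97 ± 0.05. Their median was 0.29 (camera adjusted p = 0.00284, and adjusted p = 0.143 with an estimated correlation). Histone genes had 3 of 9 higher (6 adjusted over the list alone), with HIST1H1C at 0.80 ± 0.13 and HIST1H2BK at 0.71 ± 0.12. Their median was 0.48 (camera adjusted p = 0.00397, and adjusted p = 0.108 with an estimated correlation). Neighbours of USP29 in the PEG3 domain had 1 lower and 1 higher of 8 (1 and 1 adjusted over the list alone), PEG3 at -0.30 ± 0.06 and ZNF304 at 0.44 ± 0.09 (list adjusted p = 0.656). PEG3 did not pass with both lines fitted together (0.233). B cell genes had 2 higher and 1 lower of 5 (3 and 1 adjusted over the list alone), with BCL6 at 0.64 ± 0.09 and CD24 at 0.23 ± 0.05 (0.378). In the SK-N-BE2 USP29 sgRNA libraries the summed level of 873 olfactory receptor genes was 22.9 ± 1.01 CPM, against 9.32 ± 0.804 CPM in controls, and 1844 genes without a count in controls were counted in 2 or more libraries, against 456 the other way. At low levels the T cell gene IL7R rose by 3.36 ± 0.72 as the only tested member (1 adjusted over the list alone). The myeloid genes CSF1R at 3.66 ± 0.65 and CD68 at 2.00 ± 0.42 rose among 3 (2 adjusted over the list alone). In the epithelial list CLDN4 rose by 2.49 ± 0.48 and KRT18 by 3.10 ± 0.79 among 6 (2 adjusted over the list alone, list adjusted p = 0.0937). The KRT18 call (adjusted p = 0.0201) was lost without control 1 or control 3. Of the 26 tested lists camera called 17, or 2 with an estimated correlation.

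**Figure D1:**
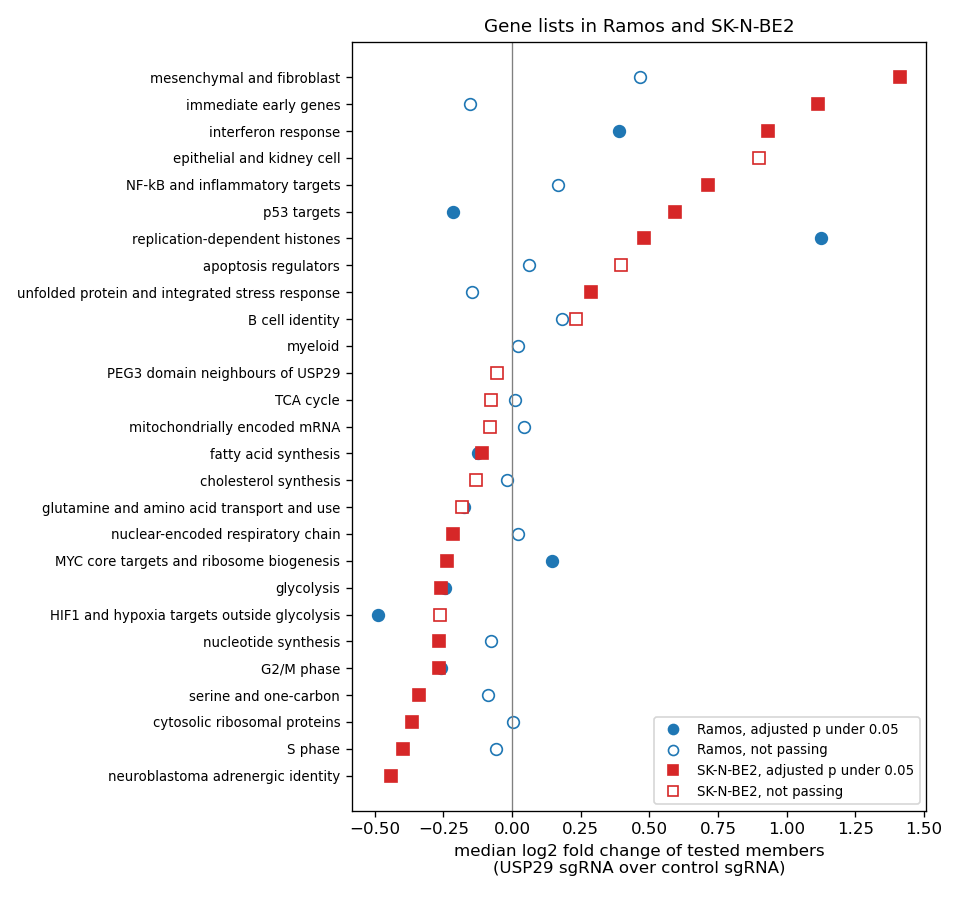
Median log2 fold change (x axis, USP29 sgRNA over control sgRNA) of the tested members of each gene list (y axis) in Ramos (blue circles) and SK-N-BE2 (red squares), for lists with 5 or more tested members, with filled symbols where the camera adjusted p with the preset correlation was under 0.05. The mesenchymal list lies at 1.41 in SK-N-BE2, and the MYC core target list at 0.15 in Ramos and -0.24 in SK-N-BE2.

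Genes of glycolysis, hypoxia and mitosis were among those that fell in both lines. Of the glycolysis genes tested in both lines 7 of 23 fell in each (PFKFB4, PGK1, ENO1, PGAM1, GPI, PDK1 and ALDOC), and of the other HIF1 and hypoxia targets 7 of 18 (VEGFA, KDM4B, ERO1A, DDIT4, P4HA1, EGLN1 and FAM162A). In the G2/M list 13 of 24 fell in both lines, in the serine list 5 of 12 and in the fatty acid list 4 of 11. Of 13 interferon genes 4 rose in both. Over the 12292 genes tested in both lines 231 rose in both, where independent lists would share 153.8 (odds ratio 1.75, Fisher's exact p = 1.67e-11). In both lines 370 fell, where 216.2 would be shared (odds ratio 2.24, Fisher's exact p = 3.22e-30, across genes, which are not independent replicates). Opposite changes were seen in 363 genes, 168 higher in Ramos and lower in SK-N-BE2 and 195 the reverse, where independent lists would hold 172.6 and 192.7. The balance of shared changes turned with both lines fitted together (392 up and 322 down) and at 1.5-fold or more (70 and 29). The total of 601 was 380, 316 or 335 without Ramos control 1, 2 or 3, 382 without Ramos USP29 sgRNA library 1 and 354 without library 2. It was 67 without both of libraries 2 and 3, a comparison of 1 Ramos library against 3 added after the data were seen.

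By the naming rule the shared increases were led by YAP1, a transcriptional coactivator of growth genes (1.85 ± 0.22 in Ramos and 3.00 ± 0.23 in SK-N-BE2). It was followed by the nuclear body gene SP110 (1.33 and 1.77), the inflammatory caspase CASP4 (1.25 and 2.84), the vitamin D receptor VDR (1.24 and 2.45) and the interferon-induced SAMD9 (1.22 and 2.11). Shared decreases were led by SMPD3 (-1.65 ± 0.17 and -1.55 ± 0.13), VLDLR (-1.14 and -0.97), DDIT4 (-0.93 and -0.99), the aldolase ALDOC (-0.88 and -1.29) and FAM162A (-0.80 ± 0.06 and -1.18 ± 0.11). Across the genes tested in both lines, which are not independent replicates, the log2 fold changes correlated weakly (Pearson r = 0.0912, Spearman rho = 0.0804). Other pairs of library splits gave r from -0.0951 to 0.115, and 3 of 100 drawn pairs, the real pair included, reached the observed r. Without a filter on low counts r was 0.0278, with both lines fitted together 0.0412, and without Ramos control 2 it was 0.0595.

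**Figure D2:**
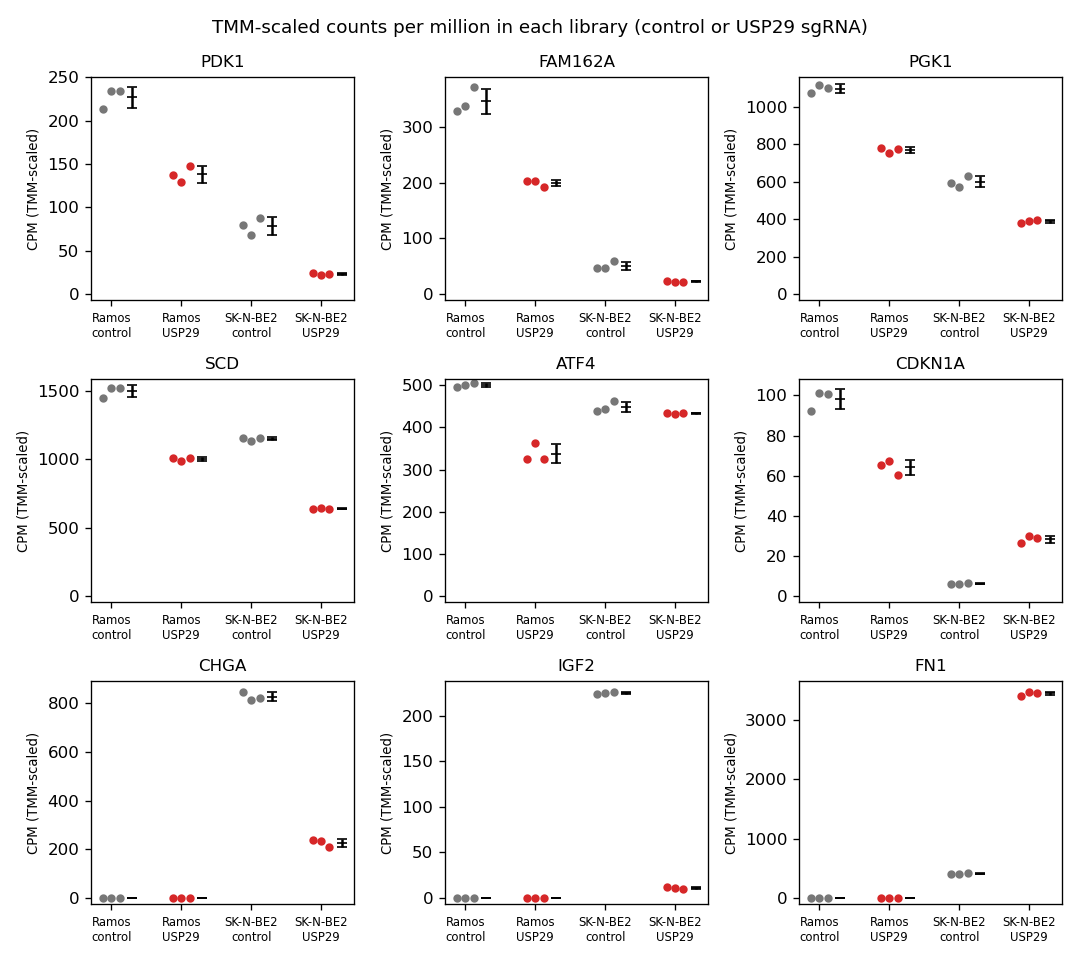
Level in CPM on library totals scaled by TMM within each line (y axis of each panel, starting near 0), of 9 named genes in each library, with grey points for control sgRNA, red points for USP29 sgRNA and mean ± SD over the 3 libraries of a group, in Ramos and SK-N-BE2. PDK1 is lower with the USP29 sgRNA in both lines, and CDKN1A falls from 98.2 to 64.3 in Ramos and rises from 6.15 to 28.2 in SK-N-BE2.

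MYC core targets, S phase genes and immediate early genes responded differently in the 2 lines. In the test of the difference (SK-N-BE2 change minus Ramos change), MYC core targets had 23 of 35 members lower (27 adjusted over the list alone) at a median of -0.43 (camera adjusted p = 5.04e-08, and adjusted p = 0.0143 with an estimated correlation). S phase genes had 14 of 22 lower (18 adjusted over the list alone) at -0.40 (1.32e-06, and adjusted p = 0.0391 with an estimated correlation). Immediate early genes had 8 higher and 1 lower of 17 (9 and 1 adjusted over the list alone) at 1.08 (5.99e-08, and adjusted p = 0.0143 with an estimated correlation). The p53 targets had 10 higher and 1 lower of 24 (11 and 1 adjusted over the list alone) at 0.58 (2.75e-05, and adjusted p = 0.0667 with an estimated correlation). Of these genes 6 of 21 had changed in opposite directions in the separate fits, CDKN1A among them. Over all genes 3381 of 17978 differed, 1471 higher and 1910 lower in SK-N-BE2 relative to Ramos (edgeR, adjusted p under 0.05). The share higher was 43.5%, against 53.8% of 3246 genes with DESeq2's size factors and 54.6 to 55.8% when any 1 SK-N-BE2 library was left out.

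Further lists that differed were the unfolded protein list (12 higher and 1 lower of 25, 13 and 1 adjusted over the list alone, camera adjusted p = 0.000152, and adjusted p = 0.145 with an estimated correlation). The ribosomal protein list differed as well (19 of 32 lower, 23 lower and 1 higher adjusted over the list alone, 2.76e-06, and adjusted p = 0.194 with an estimated correlation). Nucleotide synthesis (10 of 24 lower, 11 adjusted over the list alone, 0.00166) and the respiratory chain (12 of 31 lower, 14 adjusted over the list alone, 0.00136) also differed. Both had adjusted p = 0.187 with an estimated correlation. The adrenergic list (5 of 22 lower, 8 adjusted over the list alone, 2.75e-05) and the mesenchymal list (5 of 16 higher, 5 higher and 1 lower adjusted over the list alone, 0.000841) had adjusted p = 0.187 with an estimated correlation. Both hold genes with almost no counts in Ramos. The adrenergic median of the difference was -3.06, against -0.44 in SK-N-BE2 alone. In Ramos these genes summed to 0.820 CPM in controls and 2.87 CPM with the USP29 sgRNA. Ramos USP29 sgRNA libraries 2 and 3 also stood higher on genes abundant in SK-N-BE2, so SK-N-BE2 RNA or reads there may contribute to this call. The mesenchymal median was 0.69 and its mean -0.34, and the call was lost without Ramos USP29 sgRNA library 1 (0.0611). Histone genes had 3 of 10 lower (3 adjusted over the list alone, 0.0439, and adjusted p = 0.312 with an estimated correlation), a call lost without Ramos control 2 (0.0686), control 3 (0.0551), USP29 sgRNA library 1 (0.0511) or 2 (0.112), or SK-N-BE2 USP29 sgRNA library 2 (0.0532). The glycolysis, hypoxia and G2/M lists did not pass the test of the difference (adjusted p = 0.189, 0.671 and 0.329).

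Among single genes, the increase of CASP4 was larger in SK-N-BE2 by 1.55 ± 0.26 on the log2 scale (adjusted p = 0.00159). That of YAP1 was larger by 1.11 ± 0.35 (adjusted p = 0.0434), a call lost in 10 of the 12 omissions of a library (highest adjusted p = 0.117). The change of FAM162A was lower in SK-N-BE2 (difference -0.43 ± 0.13, adjusted p = 0.0363), a call lost in 9 of the 12 omissions and with DESeq2's size factors (0.0649). HIF1A, MYC, MAX and ARNT did not differ past the threshold (adjusted p = 0.227, 0.604, 0.0717 and 0.295). The genes with the largest fitted differences were nearly absent from at least 1 group. TTN, the titin gene, had 708, 759 and 602 counts in Ramos controls and 825, 966 and 949 with the USP29 sgRNA, against 1, 0 and 0 and then 27, 14 and 21 in SK-N-BE2. DCT had 8, 12 and 6 and then 8, 163 and 157 counts in Ramos, against 174, 160 and 150 and then 7, 5 and 8 in SK-N-BE2. The endothelin gene EDN1 and ADAMTS15 had at most 5 counts in any Ramos library. In SK-N-BE2 EDN1 rose from 19, 19 and 24 to 137, 143 and 134 counts and ADAMTS15 from 27, 26 and 22 to 146, 148 and 140 counts.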

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

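Of the tests here, that of cells of another type without MYCN mixed into the SK-N-BE2 libraries, that of an outside source shared by SK-N-BE2 controls and Ramos libraries, and the choice of the uneven genes and pigment cell markers as a subject were made only after the values that raised them were seen.

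The change with the USP29 sgRNA differed between Ramos and SK-N-BE2 in 3381 genes by the interaction test. Of 100 drawn pairs of splits 2 gave as many, the real pair and the one with the SK-N-BE2 groups exchanged (4020 genes), and the other 98 gave at most 1502. Mixed splits put the real change into the spread and the exchanged pair gave more calls than the real one, so these pairs do not test whether the lines differ. For the genes changed the same way in both lines 1 of 100 pairs gave as many as the real 601, the exchanged pair gave 363 and the other 98 gave 0. They say nothing either on whether the sharing exceeds that of independent lists, since other splits of a line call almost no genes. In each line alone the 10 possible splits are too few for a share under 0.05: the real split called 2445 genes in Ramos (1 of 10 splits as large, highest other 3) and 6240 in SK-N-BE2 (1 of 10, highest other 4).

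Lists whose change differed between the lines were MYC core targets (adjusted p = 5.04e-08), nucleotide synthesis (0.00166), the respiratory chain (0.00136), cytosolic ribosomal proteins (2.76e-06), S phase (1.32e-06), p53 targets (2.75e-05) and the unfolded protein response (0.000152). So were the adrenergic list (2.75e-05), the mesenchymal list (0.000841), histones (0.0439) and immediate early genes (5.99e-08), all by camera with the preset correlation. With an estimated correlation MYC core targets and immediate early genes (adjusted p = 0.0143 each) and S phase (adjusted p = 0.0391) kept the call, and the other 8 lists had adjusted p = 0.0667 to adjusted p = 0.312. Genes named by the rule whose change differed were YAP1 (1.11 on the log2 scale, higher in SK-N-BE2), CASP4 (1.55) and FAM162A (-0.43). The largest fitted differences were those of INO80B-WBP1 (18.4), ADAMTS15 (7.11), EDN1 (5.66), TTN (5.54), ROBO3 (5.19), MYCN (-7.98), TYRP1 (-7.79), DCT (-7.68), STMN2 (-6.63) and XKR7 (-6.61). These genes had groups at or near 0 counts, so their fitted values depend on the prior count and bound nothing. MYCN, STMN2 and XKR7 were at 0 CPM in Ramos controls and at 1.04, 0.453 and 0.226 CPM with the USP29 sgRNA. SK-N-BE2 RNA or reads in Ramos libraries may contribute to these 3 differences. ADAMTS15 lost its call without Ramos control 3 (adjusted p = 0.108) and INO80B-WBP1 without Ramos control 2 (adjusted p = 1), the library that held all of its 102 Ramos counts. ROBO3 had 4, 5 and 2 counts in Ramos controls and 0 in the other Ramos libraries, and no call in SK-N-BE2 alone (adjusted p = 0.282).

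SK-N-BE2 lost adrenergic and gained mesenchymal transcripts, a pattern that could come from other cells in the USP29 sgRNA libraries, from their lower depth, or from a change of the cells themselves. Added cells that lack MYCN would lower MYCN by the full dilution and no gene further, but 8 of 22 adrenergic genes fell further than MYCN (-0.62 ± 0.03) by more than the summed errors doubled, among them DBH at -1.91 ± 0.08. All 6 libraries were also thinned to the smallest total. The mean mesenchymal change minus the mean adrenergic change was then 1.01 times its former value (2.03 against 2.01). Thinning leaves the expected share of each gene in its library unchanged, so this value was set in advance and does not test depth. The comparison with MYCN argues against added cells without MYCN as the whole cause. Fewer reads alone likewise leave expected shares unchanged, yet the summed mesenchymal level rose from 3255 ± 393 to 8801 ± 119 CPM. The summed adrenergic level fell from 7836 ± 340 to 5575 ± 74.7 CPM (SD, n = 3). These shifts argue against lower depth by itself. Added cells that hold MYCN themselves, a change of cell state and outgrowth of a subclone during selection stay open. The change of cell state is a hypothesis found and tested on the same data.

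Counts of some abundant genes were uneven between replicates: 228 of 12026 protein-coding genes of 100 or more counts (1.90%) differed 3-fold or more within a group, for instance INO80B with 61 to 205 counts in the SK-N-BE2 USP29 sgRNA libraries. The sharing of reads between overlapping genes may explain part of this. Of uneven genes 76.8% and of other genes 64.3% overlapped another gene of the table (odds ratio 1.84, Fisher's exact p = 6.38e-05, 95% interval 1.34 to 2.55, across genes, which are not independent replicates). Since most other genes overlap as well, much of the unevenness is left unexplained. Reads shared with a pseudogene of the same name stem were not more common (odds ratio 0.715, 95% interval 0.42 to 1.15). MYC overlaps no gene and has no such pseudogene, yet its counts within a group differed beyond counting error (smallest chi-square p over 4 groups 1.71e-20, largest 0.271), and its level of about 5 CPM in Ramos is low for a Burkitt lymphoma line, which no test here explains. Biological variation between the libraries was not tested.

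Outside RNA or reads may have entered some libraries, since 891 genes were counted in 2 or more Ramos USP29 sgRNA libraries and no control, against 350 the other way. Of these 39.2% reached 1 CPM in SK-N-BE2 against 11.1% of the reverse set, but their median there was 0.142 CPM. The summed level of 873 olfactory receptor genes, which should be silent, was 1.21 times that of controls (29.9 ± 2.20 against 24.7 ± 1.11 CPM). Over 308 genes abundant in SK-N-BE2 and nearly absent from Ramos, USP29 sgRNA libraries 2 and 3 stood at 0.102% and 0.0935% of the SK-N-BE2 level. The other 4 Ramos libraries stood at 0.031 to 0.040%. These values go with some carry-over into libraries 2 and 3. How much of the gain came from carry-over, unspecific background or a change in the cells cannot be told apart at these counts. In SK-N-BE2 1844 genes were gained and 456 lost, their median in Ramos was 0, which argues against carry-over, and the olfactory sum was 2.46 times higher (22.9 ± 1.01 against 9.32 ± 0.804 CPM), which is consistent with unspecific background such as genomic DNA or with looser silencing of genes. DCT and TYRP1 counts in Ramos USP29 sgRNA libraries 2 and 3 led to a test of 10 other pigment cell markers, whose sum was 8.33 and 7.85 CPM there and 0.907 to 1.42 CPM in the other 4 Ramos libraries (5.51 times higher at least), with 96 and 82 counts of PMEL, so RNA or reads of a pigment cell are a candidate source. Further, 4 genes had 5 or more counts in each SK-N-BE2 control and none in the SK-N-BE2 USP29 sgRNA libraries or the other 4 Ramos libraries. Of these 3 (75%), TYR, MLANA and SOX10, were in both Ramos USP29 sgRNA libraries 2 and 3, against 1 of 9 genes of the reverse kind. All 3 belong to the 10 markers above, so this partly repeats that test. The fall of DCT in SK-N-BE2 may reflect the same source in its controls, which 4 genes are too few to settle. PMEL had 83, 82 and 79 counts in these controls and 7, 11 and 13 with the USP29 sgRNA. MITF and S100B had counts in every SK-N-BE2 library. Whether the SK-N-BE2 groups were prepared or sequenced apart is not known here. If they were, effects of this cannot be told apart from those of the sgRNA in any of the 6240 calls.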

How the results depend on the processing

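Of the alternatives, robust estimation, protein-coding genes alone, genes over 1000 times higher in the other line left out, Ramos libraries 2 and 3 left out, thinning and genes tested in both lines were chosen only after seeing the data. Counts within 1.5 times of those in the report are not repeated here. Ramos gave 779 genes at 1.5-fold or more, 732 at adjusted p under 0.01, 1377 with a replicate block, 1262 to 1933 with 1 library left out and 252 without USP29 sgRNA libraries 2 and 3, where 1 library stands against 3 and is assumed to vary like the controls. SK-N-BE2 gave 2714, 3930 and, with 1 library left out, 5253 to 5480. The difference between the lines gave 1832, 1714 and, with 1 library left out, 2648 to 3401. For this difference limma-trend on log2(FPKM + 1) gave 6167, and 31 of the 3381 calls passed there with the opposite sign. Among named genes, the difference changed sign with limma-trend for TTN (-0.059), which the main edgeR test had called. It also did so for SMPD3 (-0.43) and VLDLR (-0.30), which the edgeR test had not called (adjusted p = 0.934 and 0.6255). The cause was not tested. Genes changed the same way in both lines numbered 99 at 1.5-fold, 151 at adjusted p under 0.01, 312 with the block, 316 to 533 with 1 library left out and 67 without both Ramos libraries. The correlation was 0.0278 without a filter, 0.0412 with both lines fitted together and 0.0595 to 0.0974 with 1 library left out. Lists called with an estimated correlation were 0 in Ramos, 2 in SK-N-BE2 and 3 for the difference, fry called 17 in Ramos and 20 for the difference, and with 1 library left out 7 to 11, 17 to 19 and 9 to 12 were called. The lower counts of stricter thresholds and fewer libraries follow from their construction. In the fits of each line, no gene called in the main fit was called in the opposite direction by an alternative. Calls lost in at least 1 omission were 10 of 64 named genes in Ramos (DLST, EGR2, GINS1, JUN, MCM2, MT-ND4, NDUFA4, NUDT16, PPAT and SUCLG2), 2 of 75 in SK-N-BE2 (MAX and KRT18) and 4 of 13 for the difference (ADAMTS15, FAM162A, INO80B-WBP1 and YAP1). Of 169 named gene results 88 kept their side of the threshold throughout, as did 21 of 77 list results. Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at 0.0124, -0.0703 and -0.0431 in Ramos and at -0.127, 0.0098 and -0.0629 in SK-N-BE2, and no library correlated best with its own number. With the block PPAT, SUCLG2, GINS1, MT-ND4, JUN and EGR2 in Ramos, MAX in SK-N-BE2, the FAM162A difference and the Ramos MYC core and fatty acid lists (adjusted p = 0.0537 each) no longer passed, the NF-kB list passed for the difference (0.0467), and no other named call changed. Alternatives planned for normalized values as the main unit were not run, since counts were the main unit. The USP29 difference was 1.38 on the log2(CPM + 0.1) scale. At this depth and number of libraries 38.8% of simulated 1.5-fold changes were found in Ramos and 47.8% in SK-N-BE2. The simulation changed only 200 genes, drawn above a minimum expected count, far fewer than the real tests called. These shares are therefore not the sensitivity of the real comparisons.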

Other observations

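The lists of imprinted genes and of YAP and TEAD targets and the tests on them were chosen only after the SK-N-BE2 values were seen.

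Targets of YAP and TEAD, the coactivator and transcription factors that read out cell adhesion and stretch, were higher in SK-N-BE2 with the USP29 sgRNA. Of 22 tested 16 rose and 1 fell (17 and 1 adjusted over the list alone). The median log2 fold change was 1.55 (camera of limma, adjusted p = 8.07e-10 over 7 tests of added lists, and adjusted p = 0.00631 with an estimated correlation). The list was chosen on these samples and is no independent evidence. Among them the receptor kinase gene AXL rose by 3.28 ± 0.13. THBS1, which encodes the matrix protein thrombospondin and is outside the list, rose by 2.69 ± 0.03. Whether the same list was also higher in Ramos, where YAP1 rose from a low level, was tested as a hypothesis of its own. No increase was found (camera adjusted p = 0.466, 1 of 6 tested members higher and 2 lower), and 6 members are too few to exclude one. In the test of the difference the list was higher in SK-N-BE2 at a median of 0.60 (camera adjusted p = 8.07e-10, and adjusted p = 0.000692 with an estimated correlation). Of its 22 members only 4 were higher and 2 lower (4 and 3 adjusted over the list alone). Most members had too few counts to be tested in Ramos alone.

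Imprinted genes moved both ways in SK-N-BE2. IGF2 fell by 4.36 ± 0.06 on the log2 scale, and genes of the DLK1 domain on chromosome 14 fell as well, DLK1 by 2.05 ± 0.07, RTL1 by 2.01 ± 0.13 and the noncoding MEG3 by 0.92 ± 0.06. In contrast GRB10 rose by 1.87, PHLDA2 by 1.64 and MEST by 1.41. The hypothesis that imprinted genes fell together was tested on the 31 tested genes without IGF2, DLK1 and RTL1: 7 rose and 6 fell (camera adjusted p = 0.894). The 7 that rose argue against a joint fall. Whether imprinting control was lost was not tested.

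Hypoxia genes that fell in SK-N-BE2 beyond those in the lists' lead included NDUFA4L2, PFKFB4 at -1.74 ± 0.19, NDRG1 at -1.58 ± 0.18 and HK2 at -1.02 ± 0.06, although HIF1A and EPAS1 mRNA rose in the same libraries. HK2 in Ramos was at -0.14 ± 0.07 (adjusted p = 0.182), and LDHA did not pass in either line (-0.41 ± 0.24 in Ramos and -0.08 ± 0.12 in SK-N-BE2).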
